A study of Mus musculus with 56 samples.

How the data were processed

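Total RNA of cultured mouse cortical neurons was measured on 56 Affymetrix arrays: 12 Mouse430_2 arrays (the 3' arrays), 10 MoGene 1.1 ST arrays (the earlier gene-level arrays) and 34 MoGene 2.1 ST arrays (the later gene-level arrays). Per the labels the neurons came from embryos of embryonic day 13 to 15 and were grown for 7 days in vitro, with drug for 24 or 72 h. Per the submitters' processing notes the authors used Affymetrix Expression Console and RMA; versions, annotation and the arrays normalized together are not stated. The deposited values are in units of intensity on a linear scale, 1 per probe set: they are all positive and skewed. The plan, fixed before the data were examined, took the deposited values to be log2; because they were linear, log2 was taken here, and every change below is in log2 of the deposited intensity.

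The level of the deposited columns shows separate normalization of sets of arrays within the 3' type and within the later gene-level type. On the 3' arrays the ICRF-193 arrays had mean intensities of 571 to 577.3 and the topotecan arrays of 682.3 to 698.3. On the later gene-level arrays shRNA replicates 2 and 3, irinotecan, the 24 h groups and their vehicle had 137.8 to 143.7, topotecan at 1 µM, its vehicle and shRNA replicate 1 had 177.5 to 183.3, and DRB, the oxidants and their vehicles had 201.5 to 211. The earlier gene-level arrays fall into 2 sets by the first principal component of genes up to 100 kb, with 1000 nM and vehicle 1 and 2 apart from the other 7 arrays. Their mean intensities overlap (388.5 to 401.2 and 389.2 to 398.3). These 2 sets are thus a split by the expression values themselves and not a known batch. Groups follow the sample titles and treatments, which some descriptions in the labels contradict.

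Of 45101 probe sets on the 3' arrays 34958 had 1 gene symbol, 932 several and 9211 none. The counts were 21218, 1881 and 12457 of 35556 on the earlier gene-level arrays and 23521, 1814 and 16010 of 41345 on the later ones. Probe sets with 1 symbol were used, for each gene the brightest by mean log2 value over all arrays of the type, treated ones included. Genes under the 40th percentile of mean log2 value were left out. That kept 10916 of 18194 genes (limit 7.04), 11292 of 18820 (limit 6.02) and 13308 of 22180 (limit 5.01). Gene IDs matched RefSeq genes of the assembly GRCm38.p6 for 99.42, 99.84 and 99.18%, and annotated gene lengths were found for 99.8, 99.9 and 99.8% of the kept genes. As the arrays name no genome build, that annotation was used for names and lengths only, and no coordinates are given.

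Each comparison was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 2-sided, Benjamini-Hochberg threshold of 0.05) on the arrays of its own experiment; the 3 shRNA groups entered 1 fit. Differences between the effects of treatments were tested as contrasts of 4 groups. The dose trend was the slope over the rank of the dose over 10 arrays. The long-gene score of an array is the mean log2 value of genes over 100 kb minus that of all other genes; groups were compared by an exact permutation test and its relation to dose by 1e+05 permutations. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Comparisons with 1 treated array were not tested within their own experiment; the planned fit over all groups of the table borrows its spread from other groups and array sets, so its p-values for lone arrays are not used, and list medians are set against 10000 random lists of the same size matched on mean expression. The p-values measure only the spread between arrays, since nothing states that the replicates are separate cultures.

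The groups, lists, tests, the rule for named genes and most alternatives were chosen before the data were examined. The rule names, in each comparison of groups, the 10 largest rises and the 10 largest falls past the threshold with groups that do not overlap, up to 4 members of each list with the largest change past the threshold, and always a few fixed genes, among them Top1, Top2a, Top2b, Ube3a, Nlgn1, Cntnap2, Cdkn1a and Fos; predicted genes are counted and not named. For single arrays it names the 5 largest rises and falls. Further genes in the text belong to the lists or were looked at after their values were seen. The fixed lists hold 100 autism candidate genes, 70 very long genes, 70 adhesion molecules, 25 glutamate receptors, 14 GABA receptors, 47 voltage-gated ion channels and 40 genes of vesicle release. They further hold 34 activity-regulated genes, 38 p53 targets, 26 NRF2 genes, 18 heat shock genes, 27 genes of the integrated stress and unfolded protein response, 36 interferon-stimulated genes, 11 topoisomerases and repair enzymes, 77 ribosomal proteins, 70 respiratory chain genes and 25 apoptosis genes. Cell type lists hold 18 markers of excitatory neurons, 21 of inhibitory interneurons, 22 of astrocytes, 18 of oligodendrocytes, 20 of microglia, 18 of endothelial and mural cells, 20 of fibroblasts and meninges and 37 of proliferating cells and progenitors. Genes over 100 kb, over 200 kb and under 10 kb were tested as well.

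Replicate numbers could pair the arrays where every residual correlation between treated and control arrays of 1 number exceeds 0.1. This held for ICRF-193 (0.38, 0.23 and 0.38) and Top2b shRNA (0.45, 0.39 and 0.35). It did not hold for topotecan at 300 nM (lowest -0.45), topotecan at 1 µM (lowest -0.53), irinotecan (lowest -0.03) or Top1 shRNA (0.32, 0.06 and 0.29). The highest correlations with other numbers were -0.09, 0.05 and -0.09 for ICRF-193 and -0.39, 0.40 and 0.31 for Top2b shRNA. For Top2b shRNA only replicate 1, of another array set, stood out, so pairing by number is not shown there. The script was tested on simulated data with the groups of each comparison. At a simulated log2 change of 0.5, 1 and 2 it recovered 10.4, 71.6 and 98.5% of 67, 67 and 66 changed genes for topotecan at 300 nM, 85.1, 98.5 and 100% for ICRF-193, 77.6, 100 and 100% for topotecan at 1 µM and 34.3, 83.6 and 95.5% for irinotecan. It recovered 1.49, 14.9 and 62.1% for Top1 shRNA, 0, 22.4 and 69.7% for Top2b shRNA and 0, 11.9 and 75.8% for their difference.

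The alternatives were no filter on dim genes, the mean of a gene's probe sets, a new quantile normalization of each table, a replicate block, 1 fit over all groups of a table, an intensity trend of the prior variance, a minimum change of 1.5-fold, genes over 200 kb, other genes matched on mean expression, an estimated correlation, the slope over log10 of the dose, and leaving out each array. The array set as a block, shRNA replicates 2 and 3 alone and the 7 arrays of the larger dose set were added after the values were seen. Probe sets with no symbol or several were left out of the comparisons because no single gene can be named for them.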

Results

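RNA levels were measured on 56 Affymetrix arrays of 3 types in cultured cortical neurons from C57BL6 mouse embryos, exposed to inhibitors of topoisomerases or to short hairpin RNAs (shRNAs) against them. Topoisomerases relieve the twist that builds up in DNA during transcription and replication. The 3' arrays held topotecan at 300 nM (n = 3) with vehicle (n = 3) and ICRF-193 at 3 µM (n = 3) with its own vehicle (n = 3). The earlier gene-level arrays held 1 topotecan array each at 3, 30, 150, 500 and 1000 nM, 2 at 300 nM, and 3 vehicle arrays. The later gene-level arrays held topotecan at 1 µM (n = 6) with vehicle (n = 6), irinotecan at 10 µM (n = 3), topotecan for 24 h (n = 1) and topotecan for 24 h followed by washout (n = 1). Irinotecan and these last groups shared 2 vehicle arrays. They also held control, Top1 and Top2b shRNA (n = 3 each), DRB at 100 µM and its vehicle (n = 1 each), and hydrogen peroxide at 100 µM and paraquat at 10 µM (n = 1 each) with 2 vehicle arrays. The number of arrays limits the precision. Changes are log2 differences ± SE from limma with Benjamini-Hochberg adjusted p. For every changed gene named in a comparison of groups, all treated arrays lay on 1 side of all control arrays, except Top1 and Ube3a with topotecan at 1 µM, whose groups overlapped.

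Topotecan at 300 nM, an inhibitor of topoisomerase I, was compared with vehicle to see which genes respond to the drug. The largest falls were in genes with long annotated spans. Gpc5, a glypican of the cell surface spanning 1430 kb, fell by 4.63 on the log2 scale (± 0.35, adjusted p = 0.00223). Its mean log2 value went from 10.79 to 6.16 (n = 3 and 3). The latter lies under the limit of 7.04 for dim genes, where background limits the size of a fall, so no fold is given. Nrg3, a neuregulin ligand, fell 10.7-fold (-3.42 ± 0.21), Lingo2 10.1-fold (-3.34 ± 0.21) and Grm7, a metabotropic glutamate receptor, 11.1-fold (-3.47 ± 0.32). The synaptic adhesion genes Nlgn1 and Nrxn3 fell 7.36-fold (-2.88 ± 0.26) and 7.13-fold (-2.83 ± 0.23). Trhr, the receptor for thyrotropin-releasing hormone, rose 4.42-fold (2.14 ± 0.41, adjusted p = 0.033), Ctxn2 rose 3.52-fold (1.82 ± 0.21), and Slc17a6, a vesicular glutamate transporter, rose by 0.98 ± 0.16. Ube3a, an imprinted ubiquitin ligase, rose 1.53-fold (0.62 ± 0.13, adjusted p = 0.0462). Top1 (0.18, adjusted p = 0.382), Top2b (-0.31, adjusted p = 0.327) and Cdkn1a (0.45, adjusted p = 0.548) did not pass the test.

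Of 1651 genes over 100 kb, 305 fell and 10 rose with topotecan at 300 nM (594 and 37 adjusted over the list alone), which is 18.5% lower against 0.356% of the other genes. Among 48 very long genes named from general knowledge, 40 fell and 0 rose (41 and 2 adjusted over the list alone), with a median of -1.88. Of 75 autism candidate genes, 28 fell and 1 rose (40 and 3 adjusted over the list alone). The autism candidates over 100 kb had a median of -0.97 and those up to 100 kb of -0.07. Of 61 synaptic and axonal adhesion molecules 23 fell (35 adjusted over the list alone), and of 18 glutamate receptors 9 fell (11 adjusted over the list alone), among them Grin2b (-2.23 ± 0.29). Camera's adjusted p for these 5 groups lay between 1.23e-49 and 4.75e-12, and adjusted p = 0.179 to 0.493 with an estimated correlation. Markers of astrocytes moved with them: 6 of 20 fell (12 adjusted over the list alone), including Slc4a4 (-2.57 ± 0.23) and Aqp4 (-1.89 ± 0.35), with camera's adjusted p = 6.76e-12 and adjusted p = 0.179 with an estimated correlation. Fibroblast and meningeal markers had a median of -0.46 with 0 of 18 past the test over all genes and 1 lower adjusted over the list alone (camera's adjusted p = 0.00107, and adjusted p = 0.535 with an estimated correlation). Microglia markers and proliferating cell genes pointed down too, with medians of -0.29 and -0.17, 0 of 10 and 1 of 23 lower, camera's adjusted p = 0.0407 and 0.0198, and adjusted p = 0.726 and 0.535 with an estimated correlation. Neuron markers did not pass camera: 14 inhibitory interneuron markers had a median of 0.53 (camera's adjusted p = 0.0872) and 17 excitatory markers of 0.09 (0.697). At 1 µM, described below, the interneuron median was -0.33. Of 34 voltage-gated ion channels 8 fell and of 37 genes of vesicle release 5 fell and 1 rose (12 and 1, and 7 and 3, adjusted over the list alone), with camera's adjusted p = 1.55e-06 and 0.00527, and adjusted p = 0.535 and 0.704 with an estimated correlation.

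In all, 480 of 10916 genes passed an adjusted p of 0.05 with topotecan at 300 nM, 142 higher and 338 lower. The mean log2 value of genes over 100 kb minus that of all other genes, called the long-gene score below, was -0.515 ± 0.132 with drug and 0.049 ± 0.142 with vehicle (mean ± SD, n = 3 each). The difference of -0.564 had a 2-sided exact permutation p of 0.1, the smallest that 3 arrays against 3 allow. The count was 90 without vehicle 2, 112 without topotecan 2, 158 without topotecan 3 and 305 without vehicle 3.

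**Figure D1:**
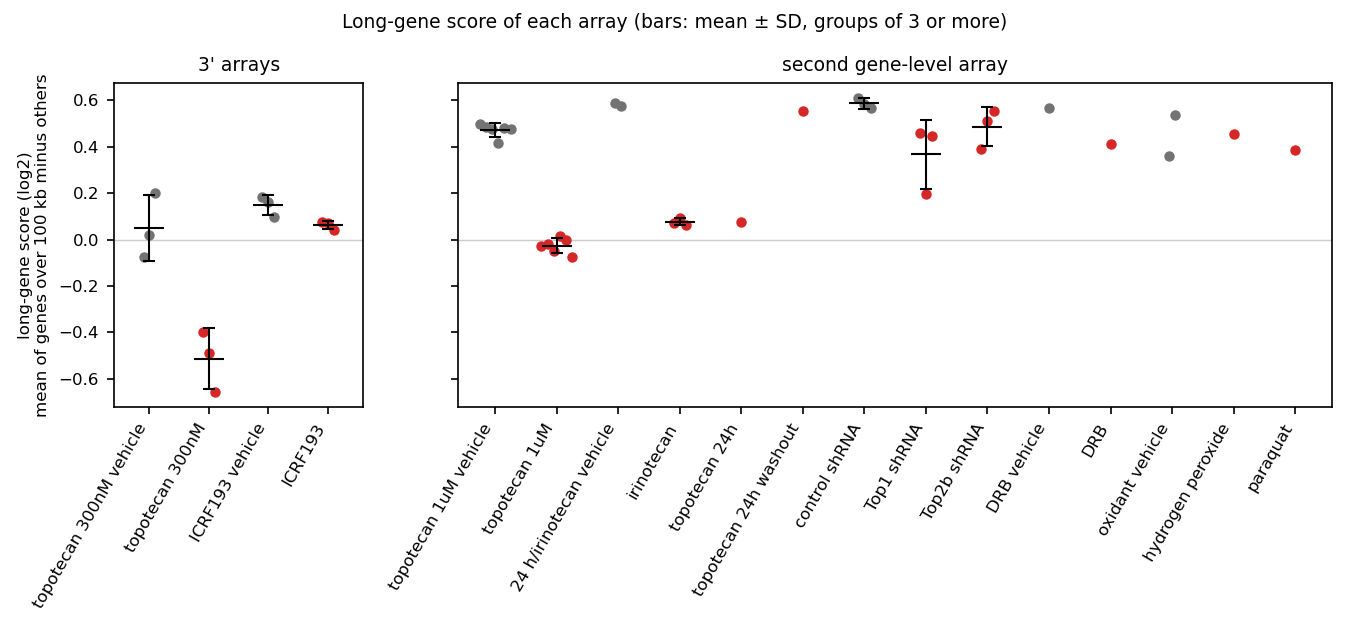
Long-gene score (log2, vertical axis) of each array by group (horizontal axis), with treated arrays in red, controls in grey and bars for mean ± SD in groups of 3 or more. With topotecan at 1 µM the 6 arrays averaged -0.026 against 0.473 in vehicle, and the array taken after washout differed from its vehicle mean by -0.027.

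ICRF-193, a catalytic inhibitor of topoisomerase II, was compared with its vehicle to see which genes respond to an inhibitor of the other enzyme class. Hapln1, a link protein of the extracellular matrix spanning 71.3 kb, fell (-2.01 ± 0.05, adjusted p = 1.77e-06). Its mean log2 value went from 7.27 to 5.26 (n = 3 and 3). The latter lies under the limit of 7.04 for dim genes, where background limits the size of a fall, so no fold is given. Gpc5 fell 3.06-fold (-1.61 ± 0.10), Lingo2 2.93-fold (-1.55 ± 0.07), Nrxn3 2.79-fold (-1.48 ± 0.07) and Nlgn1 1.98-fold (-0.99 ± 0.04). Aldh1a3, an enzyme of retinoic acid synthesis, rose 2.46-fold (1.30 ± 0.14, adjusted p = 0.0012), and Chodl rose 2.33-fold (1.22 ± 0.08). Ube3a rose by 0.23 ± 0.04 (adjusted p = 0.00547) and Cntnap2 by 0.37 ± 0.04 (adjusted p = 0.00179). With the mean of each gene's probe sets in place of the brightest, the values were -0.06 for Ube3a and -0.29 for Cntnap2. A dim Ube3a probe set fell by 0.30 (± 0.06, limma's adjusted p over all probe sets = 0.0365), from 6.16 to 5.86. Another Cntnap2 probe set fell by 1.20 (± 0.08, limma's adjusted p over all probe sets = 0.000702), from 8.97 to 7.76. No direction is claimed for Cntnap2. Top1 (0.05, adjusted p = 0.363) and Top2b (0.08, adjusted p = 0.217) did not pass.

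Of 32 genes regulated by the tumour suppressor p53, 14 rose and 2 fell with ICRF-193 (18 and 2 adjusted over the list alone), including the death-associated membrane protein Perp (1.11 ± 0.23, adjusted p = 0.0151), Ckap2 (0.57) and the cell cycle inhibitor Cdkn1a (0.49 ± 0.10). Of 27 genes of the integrated stress and unfolded protein response, 11 fell and 0 rose (11 and 1 adjusted over the list alone), among them Slc7a11 (-0.53), Chac1 (-0.52) and Phgdh (-0.48). The adjusted p was 0.000207 and 2.58e-05 for these lists, and adjusted p = 0.586 and 0.195 with an estimated correlation. Of 48 very long genes 42 fell and 2 rose (the same counts adjusted over the list alone), with a median of -0.65. Of 75 autism candidate genes 34 fell and 6 rose (40 and 6 adjusted over the list alone), and of 61 adhesion molecules 35 fell and 3 rose (36 and 5 adjusted over the list alone). For the last 3 lists camera's adjusted p was 4.23e-29, 1.92e-08 and 5.55e-12, and adjusted p = 0.489, 0.586 and 0.586 with an estimated correlation. Astrocyte markers moved too, with 14 of 20 lower (17 adjusted over the list alone) and a median of -0.38, among them Gfap (-0.92 ± 0.23) and Aqp4 (-0.82 ± 0.13); camera's adjusted p was 3.99e-09, and adjusted p = 0.49 with an estimated correlation.

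With ICRF-193, 2031 of 10916 genes passed, 905 higher and 1126 lower, and 392 of the lower ones spanned more than 100 kb. At a change of at least 1.5-fold 144 passed, 53 higher and 91 lower. After a new quantile normalization 2080 passed, 1145 higher and 935 lower, so the balance of rises and falls depends on the scaling. The long-gene score was 0.063 ± 0.017 with drug and 0.149 ± 0.044 with vehicle (mean ± SD, n = 3 each, 2-sided exact permutation p = 0.1, the smallest possible). With the replicate number as a block, 2889 genes passed, 1385 higher and 1504 lower. With 1 array left out the count was 885 (ICRF-193 2), 923 (ICRF-193 3), 1213 (vehicle 1) and 1239 (vehicle 2).

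The effects of topotecan at 300 nM and ICRF-193 at 3 µM differed for 393 genes when tested directly, with 263 lower and 130 higher under topotecan relative to ICRF-193. Gpc5 differed by -3.02 ± 0.41 (adjusted p = 0.00396; -4.63 against -1.61), Ccser1 by -2.76 ± 0.20 (-3.12 against -0.36) and Nlgn1 by -1.89 ± 0.29 (adjusted p = 0.00679). Pxdn, a peroxidase of the extracellular matrix, differed by 1.51 ± 0.19 (0.71 against -0.80). Of 48 very long genes, 29 were lower and 0 higher under topotecan (39 and 2 adjusted over the list alone; camera's adjusted p = 9.96e-35), and adjusted p = 0.131 with an estimated correlation. Astrocyte markers differed as well, with 3 of 20 lower and 0 higher (4 and 0 adjusted over the list alone, median -0.30, camera's adjusted p = 8.74e-06), and adjusted p = 0.131 with an estimated correlation. For the synaptic vesicle release machinery the median was 0.01, the mean -0.20 and the direction of the test down (camera's adjusted p = 0.00983, and adjusted p = 0.634 with an estimated correlation), and the median turned to -0.01 after a new quantile normalization. Inhibitory interneuron markers had a median difference of 0.48 and did not pass (camera's adjusted p = 0.132). The difference of the long-gene score was -0.478 (95% interval -0.743 to -0.213, permutation p = 0.0865). Across 10916 genes the changes had a Pearson r of 0.59, and 214 genes fell with both drugs where 34.9 were expected from the counts; genes are not independent replicates. Drug and experiment cannot be told apart here, because each drug was run with its own vehicle in its own set of arrays. Leaving out 1 array gave 136, 140 and 160 genes (ICRF-193 1, 2 and 3), 150, 143 and 147 (its vehicle 1, 2 and 3), 615 and 244 (topotecan 1 and 2), and 1048 and 637 (topotecan vehicle 1 and 3).

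Topotecan at 1 µM was measured with 6 arrays per group. Nkain2, a protein that interacts with a sodium pump subunit and spans 1210 kb, fell 9.81-fold (-3.29 ± 0.10, adjusted p = 3.19e-11), from 10.27 to 6.98 (n = 6 and 6). Csmd1, a complement regulator spanning 1640 kb, fell 8.92-fold (-3.16 ± 0.08), Erbb4 by 2.74, Nrxn3 by 2.45 and Cntnap2, a neurexin-like adhesion protein, 3.83-fold (-1.94 ± 0.19). Genes with shorter spans fell too: Ipw, a non-coding RNA of an imprinted region spanning 59.7 kb, 9.7-fold (-3.28 ± 0.14), the astrocyte filament gene Gfap 6.59-fold (-2.72 ± 0.09) and the neuropeptide gene Sst 6.1-fold (-2.61 ± 0.10). Rgs16, a regulator of G-protein signalling, rose 3.52-fold (1.82 ± 0.12), Edn1, which encodes endothelin, 3.35-fold (1.75 ± 0.09), and the small heat shock gene Hspb1 2.37-fold (1.25 ± 0.14). Top1 rose by 0.22 ± 0.05 (adjusted p = 0.00414) and Top2a fell by 0.66 (± 0.11), while Top2b did not pass (0.05, adjusted p = 0.592). Ube3a was called higher by 0.21 ± 0.07 (adjusted p = 0.0266) from the probe set brightest over all arrays of the type, but the mean of its probe sets gave -2.26.

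A second Ube3a probe set fell by 4.73 (± 0.15, 26.6-fold) with topotecan at 1 µM, from 10.04 ± 0.28 to 5.31 ± 0.27 (mean ± SD, n = 6 and 6). In vehicle this second probe set was the brighter, as the one used for the calls stood at 9.31 there. With irinotecan the second probe set fell from 10.05 to 4.60 (adjusted p = 0.00117), and the array at 24 h of topotecan stood at 4.63. Both lie under the limit of 5.01 for dim genes, where background limits the size of a fall, so no fold is given. After washout the array stood at -0.49 against vehicle. Snhg14, a non-coding gene of the same imprinted region, fell by 1.22 (± 0.12) with topotecan at 1 µM and by 1.11 (± 0.22, adjusted p = 0.0408) at 300 nM. On the 3' arrays a second Ube3a probe set rose by 0.84 ± 0.12 (adjusted p = 0.015) with topotecan at 300 nM. Cntnap2 also had probe sets that moved apart there: 1 gave log2 means of 10.68 in vehicle and 10.96 with topotecan, and another fell by 2.90 (± 0.44, adjusted p = 0.0177), from 9.78 to 6.88. These probe sets of Cntnap2 were looked at after the values were seen.

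**Figure D2:**
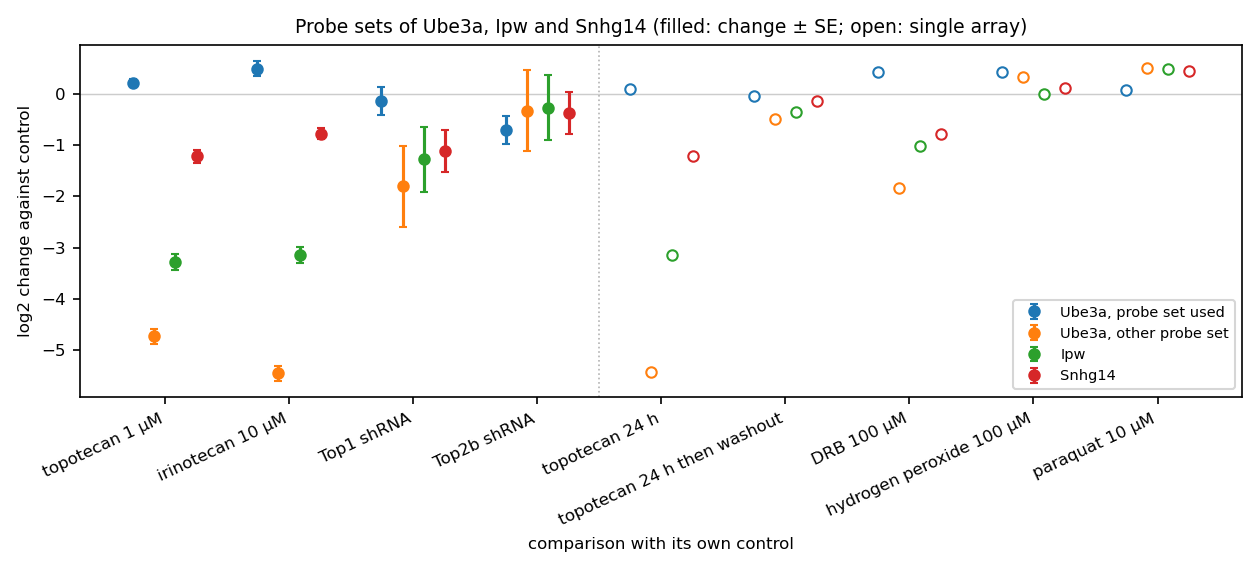
Log2 change against control (vertical axis) of 2 probe sets of Ube3a and of Ipw and Snhg14 in each comparison on the later gene-level arrays (horizontal axis). Filled points are changes ± SE and open points single arrays. The Ube3a probe set used for the calls lay at 0.21 with topotecan at 1 µM and the other at -4.73.

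Of 1988 genes over 100 kb, 1281 fell and 94 rose with topotecan at 1 µM (1342 and 111 adjusted over the list alone), which is 64.4% lower against 13.2% of the others. Counts of called genes depend on the number of arrays and cannot rank the treatments: over 200 kb the median was -0.74 at 300 nM and -0.68 at 1 µM, and a simulated change of 0.5 was recovered in 10.4 and 77.6% of genes. These medians come from different array types and experiments, so they do not rank the doses either. In the dose series, described below, the median over 200 kb was -0.16 and -0.14 at 300 nM and -0.46 at 1000 nM. The size at 300 nM thus differed between the experiments. Of 840 genes over 200 kb, 712 fell and 13 rose (724 and 16 adjusted over the list alone; median -0.68), and of 61 very long genes 59 fell and 0 rose (60 adjusted over the list alone; median -1.93). Of 3589 genes under 10 kb, 901 rose and 395 fell (888 and 384 adjusted over the list alone; median 0.06). These groups had camera's adjusted p of 2.24e-38, 4.55e-66, 3.43e-45 and 0.000129, and adjusted p = 0.0124, 0.00877, 0.0158 and 0.0479 with an estimated correlation. By adjusted p these 4 are the only calls, among all fixed lists and length classes in the comparisons of groups, that held with an estimated correlation. Tested alone and without adjustment, the genes over 100 kb also passed with an estimated correlation for topotecan at 300 nM (camera's unadjusted p = 0.0187) and irinotecan (0.00822).

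Genes of the synapse fell with topotecan at 1 µM. Of 86 autism candidate genes 64 fell and 4 rose (66 and 5 adjusted over the list alone; median -0.91), with -1.22 for those over 100 kb and -0.04 for the shorter ones. Among 67 adhesion molecules 47 fell and 2 rose (the same counts adjusted over the list alone), and among 20 glutamate receptors 18 fell and 1 rose (the same adjusted over the list alone), including Grm7 (-2.63), Grin2a (-2.42) and Grm5 (-2.37). Of 11 GABA receptors 7 fell and 1 rose (the same adjusted over the list alone), among them Gabrg3 (-1.77) and Gabrb1 (-1.71), of 40 voltage-gated ion channels 28 fell and 1 rose (31 and 1 adjusted over the list alone), and of 37 genes of vesicle release 21 fell and 1 rose (24 and 1 adjusted over the list alone), including Syt1 (-2.02). Of 16 excitatory neuron markers 9 fell and 2 rose, and of 14 inhibitory interneuron markers 7 fell and 1 rose (the same counts adjusted over the list alone for both). Over these 8 lists camera's adjusted p ran from 6.43e-23 to 0.0178, and adjusted p = 0.073 to 0.526 with an estimated correlation. Astrocyte markers moved with them, 15 of 20 lower and 2 higher (the same adjusted over the list alone; median -0.66), with camera's adjusted p = 6.84e-09 and adjusted p = 0.0526 with an estimated correlation.

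Of 51 cytosolic ribosomal protein genes 29 rose and 0 fell with topotecan at 1 µM (30 adjusted over the list alone), including Rps18 (0.73) and Rps12 (0.58). Of 35 p53 target genes 13 rose and 2 fell (15 and 5 adjusted over the list alone), including Perp (0.73) and Cdkn1a (0.45 ± 0.08, adjusted p = 0.000354). Camera's adjusted p was 2.98e-08 for ribosomal proteins and 0.00328 for p53 targets, and adjusted p = 0.0636 and 0.526 with an estimated correlation. The remaining lists did not pass camera, with adjusted p from 0.054 to 0.949. Of 33 activity-regulated genes 9 rose, such as Jun (1.07 ± 0.08), and 14 fell, such as Egr3 (-1.78 ± 0.15; 10 and 14 adjusted over the list alone). Of 35 genes of proliferating cells and progenitors 4 rose and 14 fell (5 and 14 adjusted over the list alone; median -0.18). NRF2 oxidative stress genes rose in 5 and fell in 4 of 22 cases (6 and 4 adjusted over the list alone), heat shock genes in 4 and 3 of 16 and integrated stress genes in 3 and 3 of 25. Interferon-stimulated genes rose in 2 and fell in 1 of 20, topoisomerases and their repair enzymes in 1 and 1 of 10, and apoptosis genes in 5 and 0 of 20 (4 and 0 adjusted over the list alone). Mitochondrial respiratory chain genes rose in 6 and fell in 7 of 62 (5 and 5 adjusted over the list alone). Oligodendrocyte markers fell in 3 of 6 (4 adjusted over the list alone), microglia markers rose in 1 and fell in 2 of 12, endothelial markers in 1 and 3 of 10 and fibroblast markers in 3 and 4 of 19. Counts adjusted over the list alone were the same where none is given.

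With topotecan at 1 µM, 5207 of 13308 genes passed, 2434 higher and 2773 lower, and 1378 changed at least 1.5-fold, 419 higher and 959 lower. The long-gene score was -0.026 ± 0.033 with drug and 0.473 ± 0.029 with vehicle (mean ± SD, n = 6 each). The difference of -0.499 had a 2-sided exact permutation p of 0.00216, the smallest that the 924 splits allow. All 12 arrays lie in 1 array set. Vehicle array 4 had lower neuronal gene lists than the other vehicle arrays.

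**Figure D3:**
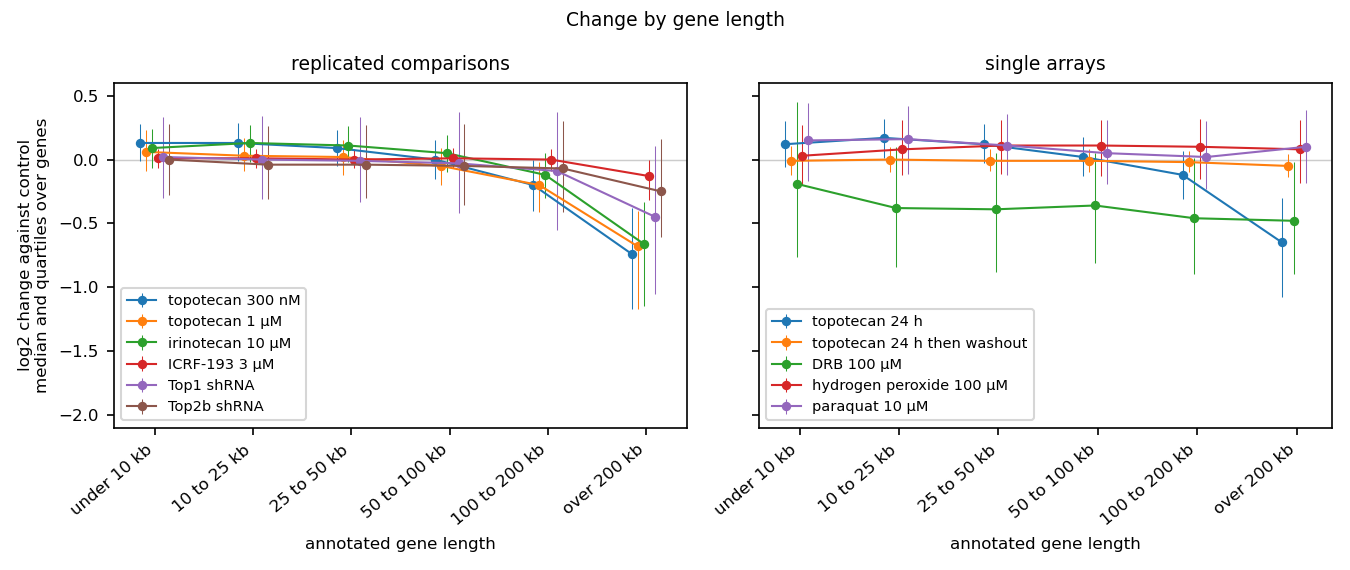
Median log2 change against control, with quartiles over genes (vertical axis), in 6 classes of annotated gene length (horizontal axis) for comparisons of groups (left) and single arrays (right). Over 200 kb the median was -0.74 with topotecan at 300 nM, -0.68 at 1 µM, -0.66 with irinotecan and -0.13 with ICRF-193.

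Irinotecan, another derivative of camptothecin, was compared at 10 µM with 2 vehicle arrays. Erbb4, a neuregulin receptor spanning 1080 kb, fell 15-fold (-3.91 ± 0.14, adjusted p = 1.54e-05), from 9.07 to 5.17 (n = 3 and 2). Nkain2 fell 12.9-fold (-3.69 ± 0.08), Il1rapl1 10.8-fold (-3.44 ± 0.22), Ipw 8.83-fold (-3.14 ± 0.14), Nlgn1 4.74-fold (-2.24 ± 0.11) and Cntnap2 4.4-fold (-2.14 ± 0.13). Txnip, an inhibitor of thioredoxin, rose 4.3-fold (2.11 ± 0.20, adjusted p = 0.000498), Slc17a6 2.67-fold (1.41 ± 0.10) and the transcription factor gene Jun 2.58-fold (1.37 ± 0.08). Ube3a was called higher, 1.41-fold (0.49 ± 0.11, adjusted p = 0.0187), and the mean of its probe sets gave -2.48. Top1 did not pass (0.19, adjusted p = 0.0969).

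Of 61 very long genes 60 fell and 0 rose with irinotecan, of 86 autism candidates 58 fell and 6 rose, and of 20 glutamate receptors 17 fell and 0 rose (60, 58 and 19 lower adjusted over the list alone). Of 67 adhesion molecules 46 fell and 6 rose (46 and 9 adjusted over the list alone), of 40 voltage-gated ion channels 24 fell and 4 rose (26 and 4 adjusted over the list alone), and of 37 genes of vesicle release 16 fell and 3 rose (17 and 4 adjusted over the list alone). Over these 6 lists camera's adjusted p lay between 1.6e-52 and 7.19e-07, and adjusted p = 0.0558 to 0.151 with an estimated correlation. Activity-regulated genes fell in 16 and rose in 7 of 33 cases (18 and 7 adjusted over the list alone), with Egr3 at -1.17 and Fos at -0.83 ± 0.17 (camera's adjusted p = 0.000609, and adjusted p = 0.151 with an estimated correlation). The p53 targets rose in 13 and fell in 2 of 35 (15 and 2 adjusted over the list alone), including the cell death genes Bbc3 (0.59) and Trp53inp1 (0.60), and interferon-stimulated genes rose in 6 and fell in 0 of 20 (7 and 0 adjusted over the list alone). Their camera adjusted p was 0.0182 and 0.0059, and adjusted p = 0.357 and 0.194 with an estimated correlation. Hrk, a cell death gene of the apoptosis list, rose 2.46-fold (1.30 ± 0.13). Markers of astrocytes (5 of 20 lower, 2 higher; 7 and 2 adjusted over the list alone) and fibroblasts (4 of 19 lower, 1 higher; 6 and 2 adjusted over the list alone) moved with the neuronal lists, with camera's adjusted p = 0.0123 and 0.0249, and adjusted p = 0.393 for both with an estimated correlation.

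With irinotecan 3750 of 13308 genes passed, 2198 higher and 1552 lower, and 959 of the 1988 genes over 100 kb fell (48.2% against 5.24% of the others). At a change of at least 1.5-fold 1117 passed. The long-gene score was 0.077 ± 0.016 with drug (n = 3) and 0.582 ± 0.009 with vehicle (n = 2), with a 2-sided exact permutation p of 0.1, the smallest possible. Without vehicle 1 the count was 1780 and without vehicle 2 it was 1994.

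Topotecan at 1 µM and irinotecan at 10 µM, given at different doses, differed by 0.006 in the change of the long-gene score (95% interval -0.06 to 0.071, permutation p = 0.933). That difference turned to -0.051 without the filter on dim genes and to -0.033 after a new quantile normalization. For 321 genes the effects differed in a direct test, 112 higher and 209 lower with topotecan relative to irinotecan. Kcnj10, a potassium channel, differed by -2.31 ± 0.22 (95% interval -2.77 to -1.85, adjusted p = 4.41e-05; -1.95 against 0.37), Gfap by -2.07 ± 0.22 (-2.72 against -0.65) and Aqp4 by -1.50 ± 0.18. Of 20 astrocyte markers 8 were lower and 0 higher (12 adjusted over the list alone; median -0.52, camera's adjusted p = 1.83e-07), and adjusted p = 0.27 with an estimated correlation. Edn1 was higher by 1.78 ± 0.16 (1.75 against -0.04) and Rgs16 by 1.44 ± 0.20 (1.82 against 0.37). The difference was 0.18 for Nlgn1 (95% interval -0.23 to 0.59, adjusted p = 0.628) and 0.20 for Cntnap2 (adjusted p = 0.767). Of the very long genes 7 of 61 were higher and 1 lower (8 and 1 adjusted over the list alone; camera's adjusted p = 1.05e-06, and adjusted p = 0.651 with an estimated correlation), but their median of 0.07 turned to -0.07 after the new quantile normalization. For genes over 200 kb the median was -0.05 and the mean -0.02 while the test pointed up (camera's adjusted p = 0.0429), and the same held for genes under 10 kb (median -0.05, mean -0.02, camera's adjusted p = 0.0331); with an estimated correlation they gave adjusted p = 0.939 and 0.387. Across 13308 genes the changes had a Pearson r of 0.76 with separate controls, and 1282 genes fell with both drugs where 323 were expected. The drugs lie in different array sets, so drug, dose and experiment cannot be told apart. Leaving out 1 array gave 180, 131 and 95 genes (irinotecan 1, 2 and 3), 45 and 102 (its vehicle 1 and 2), 186 (topotecan 2), and 203, 155 and 832 (topotecan vehicle 1, 2 and 4).

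The dose series, with topotecan from 3 to 1000 nM, asked at which dose the change begins. The long-gene score was 0.262 ± 0.024 in vehicle (n = 3), 0.26 at 3 and at 30 nM, 0.18 at 150 nM, 0.149 and 0.152 at 300 nM, 0.076 at 500 nM and -0.055 at 1000 nM. The doses from 3 to 500 nM share their array set with vehicle 3 only, which stood at 0.29, while vehicle 1 and 2 lie with 1000 nM; against vehicle 3 the score was lower by 0.03 at 3 and at 30 nM. Csmd1 stood at -1.09 against vehicle at 150 nM and at -3.19 at 1000 nM, with a slope of -0.49 ± 0.05 per dose rank (adjusted p = 0.00221). Macrod2 fell by 0.46 per rank (± 0.06), Lrp1b by 0.44 (± 0.06), Erbb4 by 0.41 (± 0.08) and Nlgn1 by 0.18 (± 0.02). Mc4r, a melanocortin receptor, rose by 0.23 ± 0.02 per rank to 1.39 at 1000 nM, Slc17a6 by 0.21 ± 0.02 (adjusted p = 0.00282), and Ube3a by 0.09 ± 0.02 (adjusted p = 0.0167). Top1 (0.03, adjusted p = 0.367) and Cntnap2 (-0.05, adjusted p = 0.592) did not pass.

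Of 59 very long genes 37 fell with dose and 0 rose (49 adjusted over the list alone), of 83 autism candidates 20 fell and 2 rose (37 and 6 adjusted over the list alone), and of 67 adhesion molecules 19 fell and 1 rose (29 and 5 adjusted over the list alone). Camera's adjusted p was 2e-41, 1.51e-10 and 1.32e-09, and adjusted p = 0.134, 0.767 and 0.767 with an estimated correlation. Astrocyte markers gave camera's adjusted p = 5.81e-05, and adjusted p = 0.893 with an estimated correlation, with 0 of 20 past limma's test over all genes; with the array set as a block 15 of 20 fell. Proliferating cell genes and microglia markers had camera's adjusted p = 0.00072 and 0.00122, and adjusted p = 0.93 and 0.785 with an estimated correlation. By limma 0 of 27 and 0 of 11 passed over all genes, and with the array set as a block 14 and 5 fell. The sets differed in Top2a, which stood at 1.19 and 1.43 against the vehicle mean in vehicle 1 and 2 and at -2.63 in vehicle 3. It lay between -2.6 and -2.2 from 3 to 500 nM and at -0.11 at 1000 nM. A blocked fall of Top2a thus rests on the 1 array at 1000 nM, and the lists were not examined for this. In all 390 of 11292 genes had a slope past the test, 170 higher and 220 lower, of which 171 lower spanned more than 100 kb.

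The score followed the rank of the dose over 10 arrays with a Pearson r of -0.91 (permutation p = 5e-05) and a Spearman rho of -0.85 (permutation p = 0.00326). The pair was the only relation across arrays that was computed, so no further adjustment applies. Without the 2 arrays farthest from the median dose (500 and 1000 nM) r was -0.90. Within the 7 arrays of the larger set r was -0.97, and the other set, with 1000 nM and vehicle 1 and 2, has too few arrays. With the set as a block 2871 genes passed, 1413 higher and 1458 lower, and within the 7 arrays 1127 passed. The sets were cut from the same expression values and are not a known batch. Counts that use them, for genes or for lists, can therefore be too high. With 1 array left out the count was 815 (1000 nM), 254 (150 nM), 247 and 232 (300 nM 1 and 2), 238 (3 nM), 135 (500 nM), and 215 and 205 (vehicle 1 and 2).

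**Figure D4:**
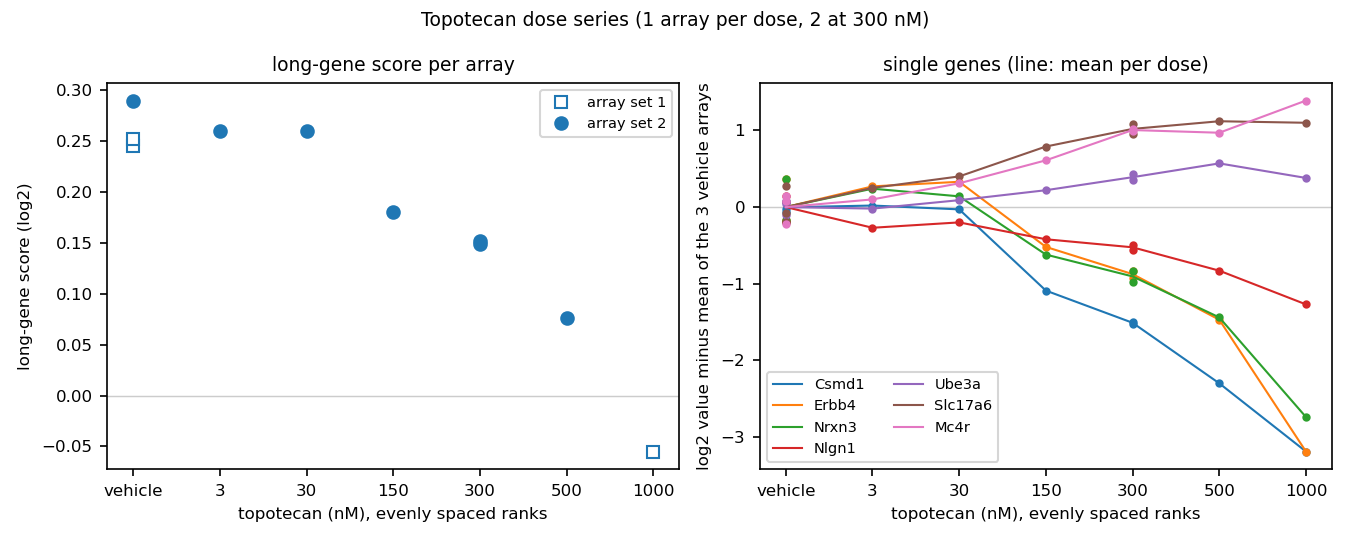
Long-gene score of each array (left, log2) and log2 values of single genes minus the vehicle mean (right) against topotecan dose in nM on evenly spaced ranks, with squares and circles for the 2 array sets. The score was 0.26 at 30 nM and -0.055 at 1000 nM, and Csmd1 reached -3.19.

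Top1 and Top2b shRNAs were compared with a control shRNA to ask whether lower levels of either enzyme act as the drugs do. The largest rises with Top1 shRNA included Ogn, an extracellular matrix proteoglycan (7.54-fold, 2.92 ± 0.50, adjusted p = 0.00752), Col8a1, a collagen (7.07-fold, 2.82 ± 0.34), and Pdgfrb, a receptor of mural cells and fibroblasts (4.8-fold, 2.26 ± 0.23), with n = 3 per group. Hmox1, the stress enzyme haem oxygenase, rose 5.17-fold (2.37 ± 0.29). Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, fell 8.15-fold (-3.03 ± 0.60, adjusted p = 0.0129), the calcium channel gene Cacna1g 6.36-fold (-2.67 ± 0.35) and the glutamate receptor Grm3 5.47-fold (-2.45 ± 0.31). Top1 itself did not pass (-0.57 ± 0.26, adjusted p = 0.193), and stood at 38.9, 95.1 and 83.1% of the control array with the same number. Nlgn1 (-0.88, adjusted p = 0.125) and Cntnap2 (-1.22, adjusted p = 0.119) did not pass.

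Of 19 fibroblast and meningeal markers 12 rose and 0 fell with Top1 shRNA (16 adjusted over the list alone; median 1.51), of 20 interferon-stimulated genes 8 rose and 1 fell (16 and 1 adjusted over the list alone), including Ddx58 (2.16) and Ifit1 (2.09), and of 22 NRF2 genes 7 rose and 0 fell (11 adjusted over the list alone). Of 35 genes of proliferating cells 5 rose (16 adjusted over the list alone), including Bub1 (1.75) and Mcm2 (1.49), and of 35 p53 targets 7 rose and 1 fell (15 and 2 adjusted over the list alone). Of 40 voltage-gated ion channels 19 fell and 0 rose (33 adjusted over the list alone), of 37 genes of vesicle release 14 fell (28 adjusted over the list alone), and of 16 excitatory neuron markers 7 fell (10 adjusted over the list alone). Of 86 autism candidates 20 fell and 0 rose (35 and 1 adjusted over the list alone), and of 67 adhesion molecules 22 fell (46 and 1 adjusted over the list alone). Over these 10 lists camera's adjusted p lay between 6.36e-14 and 4.28e-06, and adjusted p = 0.2 to 0.346 with an estimated correlation. Of 61 very long genes 17 fell and 1 rose (37 and 3 adjusted over the list alone; camera's adjusted p = 2.93e-12), and adjusted p = 0.33 with an estimated correlation. Markers of further cell types moved with these lists: 3 of 10 endothelial and mural markers rose (median 0.70, camera's adjusted p = 0.00646), and 2 of 20 astrocyte markers rose and 1 fell (median 0.49, camera's adjusted p = 0.0188), with adjusted p = 0.2 and 0.646 with an estimated correlation. Microglia markers had a median of 0.75 (0.50 within replicates 2 and 3 and 1.65 for replicate 1) and oligodendrocyte markers of 0.53, with 0 members past limma's test and camera's adjusted p = 0.0556 and 0.337. Neuronal genes up to 100 kb had a median of -1.04 and longer ones of -1.22. The fibroblast median was 0.97 within replicates 2 and 3 and 2.15 for replicate 1, which lies in another array set. The p53 targets had medians of 1.17 and -0.06 and interferon-stimulated genes of 1.76 and 0.47 in the same order, so the rise of the p53 targets rests on replicates 2 and 3.

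With Top1 shRNA 1579 of 13308 genes passed, 809 higher and 770 lower, 248 of the lower ones over 100 kb. The array set as a block gave 3777, and replicates 2 and 3 alone, within 1 set, gave 5944; both were chosen after the values were seen. The long-gene score was 0.367 ± 0.148 against 0.588 ± 0.022 in control (mean ± SD, n = 3 each, 2-sided exact permutation p = 0.1, the smallest possible). Against the control array with the same number it differed by -0.152, -0.385 and -0.123. The largest difference was in replicate 2, where Top1 stood at 95.1% of control, and not in replicate 1, at 38.9%. Without Top1 shRNA 2 the group difference moved from -0.22 to -0.135. Neuronal genes up to 100 kb fell as well, so this difference cannot be told apart from a lower share of neurons. Leaving out 1 array gave 525 and 450 genes (control 2 and 3), and 2486, 510 and 615 (Top1 shRNA 1, 2 and 3).

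With Top2b shRNA Ogn rose 9.13-fold (3.19 ± 0.50, adjusted p = 0.0166), Col8a1 5.49-fold (2.46 ± 0.34) and Hmox1 3.32-fold (1.73 ± 0.29). Got1, a transaminase, fell 4.6-fold (-2.20 ± 0.30), the sodium channel subunit gene Scn2b 3.47-fold (-1.80 ± 0.30) and the synaptotagmin gene Syt1 3.15-fold (-1.66 ± 0.33). Top2b itself did not pass (-1.19 ± 0.47, adjusted p = 0.22), at 62.5, 34.9 and 38.7% of control by number, while the Top1 shRNA arrays had Top2b at 48.6, 129 and 135%; within replicates 2 and 3 it fell by 1.44 (adjusted p = 0.00185). Of 19 fibroblast markers 6 rose and 0 fell (12 adjusted over the list alone; median 1.02), of 22 NRF2 genes 5 rose (8 adjusted over the list alone), of 40 ion channels 5 fell (13 adjusted over the list alone) and of 37 genes of vesicle release 3 fell (7 adjusted over the list alone). Camera's adjusted p lay between 5.77e-10 and 5.38e-06, and adjusted p = 0.357 to 0.362 with an estimated correlation. Neuron markers pointed down with them, with medians of -0.88 for 16 excitatory markers (1 fell) and -0.63 for 14 inhibitory interneuron markers (0 fell), and camera's adjusted p = 0.000523 and 0.0108, and adjusted p = 0.357 and 0.54 with an estimated correlation. Interferon-stimulated genes (median 0.95) and proliferating cell genes (0.62, with 0.12 within replicates 2 and 3 and 1.75 for replicate 1) pointed up with 0 members past limma's test over all genes, with camera's adjusted p = 5.67e-05 and 2.02e-05, and adjusted p = 0.519 and 0.632 with an estimated correlation. Of 20 astrocyte markers 1 rose (4 adjusted over the list alone; median 0.84, camera's adjusted p = 1.9e-05), and adjusted p = 0.579 with an estimated correlation; the median was 0.25 within replicates 2 and 3 and 1.65 for replicate 1. Microglia markers had camera's adjusted p = 0.0545 and 0.0165 with the replicate number as a block, and adjusted p = 0.686 with an estimated correlation, with medians of -0.11 within replicates 2 and 3 and 2.64 for replicate 1. In all 414 genes passed, 265 higher and 149 lower, with 1352 under the replicate block (742 higher and 610 lower), 1982 under the array set block and 3003 in replicates 2 and 3 alone. The long-gene score was 0.486 ± 0.084 (mean ± SD, n = 3), a difference from control of -0.102 with a 2-sided exact permutation p of 0.1, the smallest possible. The genes over 100 kb did not pass camera, and passed it without Top2b shRNA 3, where the difference was -0.136. By limma, 0 genes passed without control 2, control 3, Top2b shRNA 2 or Top2b shRNA 3, and 259 passed without Top1 shRNA 3, which shares the fit; 2348 genes had an unadjusted p under 0.05 with all arrays.

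Tested directly, Top1 and Top2b shRNA differed for 0 genes by limma, with 806 genes at an unadjusted p under 0.05. Top1 differed by -0.68 (adjusted p = 0.77) and Top2b by 1.11 (adjusted p = 0.801). As groups, proliferating cell genes (median 0.62, camera's adjusted p = 4.9e-08), p53 targets (0.44, 4.7e-08) and fibroblast markers (0.32, 0.00233) pointed up with Top1 shRNA relative to Top2b shRNA, and very long genes down (-0.60, 1.25e-12), each with adjusted p = 0.4 with an estimated correlation and 0 members past limma's test over all genes. The array sets disagree on part of this. Within replicates 2 and 3 the fibroblast medians were 0.97 with Top1 and 1.07 with Top2b shRNA, against 2.15 and 1.31 for replicate 1. For replicate 1 very long genes lay at -0.64 with Top1 and -0.69 with Top2b shRNA, and proliferating cell genes were the higher with Top2b shRNA (1.75), so for these 3 lists no direction is claimed. The replicate block and the array set block also gave 0, and replicates 2 and 3 alone gave 1888.

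Topotecan at 1 µM and Top1 shRNA differed for 2835 genes, 1078 higher and 1757 lower under the drug. Gfap differed by -3.90 ± 0.32 (adjusted p = 4.98e-07; -2.72 against 1.18), Myl9, a myosin light chain of smooth muscle, by -3.04 ± 0.24 (-0.36 against 2.68), Slc17a7 by 2.52 ± 0.62 (-0.51 against -3.03), Top1 by 0.79 ± 0.20 and Nlgn1 by -1.18 ± 0.31 (adjusted p = 0.00992). Of 19 fibroblast markers 16 were lower under the drug (17 adjusted over the list alone), of 35 proliferating cell genes 27 (30 adjusted over the list alone) and of 20 astrocyte markers 15 (15 adjusted over the list alone). Camera's adjusted p lay between 1.05e-16 and 7.74e-10, and adjusted p = 0.156 with an estimated correlation. Of 20 interferon-stimulated genes 13 were lower and 1 higher (17 and 1 adjusted over the list alone; median -1.51, camera's adjusted p = 6.9e-06), and adjusted p = 0.426 with an estimated correlation. Neuronal lists lay higher under the drug: 6 of 16 excitatory markers were higher and 1 lower (median 0.79), 3 and 2 of 14 inhibitory interneuron markers (0.74), 5 and 0 of 11 GABA receptors (0.69), 9 and 5 of 40 ion channels (0.55) and 9 and 1 of 37 genes of vesicle release (0.47). Camera's adjusted p for these ran from 0.00016 to 0.044, and adjusted p = 0.479 to 0.636 with an estimated correlation. Very long genes went the other way, with 19 of 61 lower and 0 higher (median -0.72, camera's adjusted p = 3.12e-08, and adjusted p = 0.479 with an estimated correlation). The long-gene score differed by -0.279 (95% interval -0.412 to -0.145, permutation p = 0.0624). Without Top1 shRNA 1 the count was 4481. The experiments differ in treatment, controls and, for shRNA replicates 2 and 3, array set, which cannot be told apart. Replicate 1 shares the intensity level of topotecan at 1 µM. It still stood apart from the other arrays over probe sets without a gene symbol (median correlation 0.36), so it does not separate these either.

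**Figure D5:**
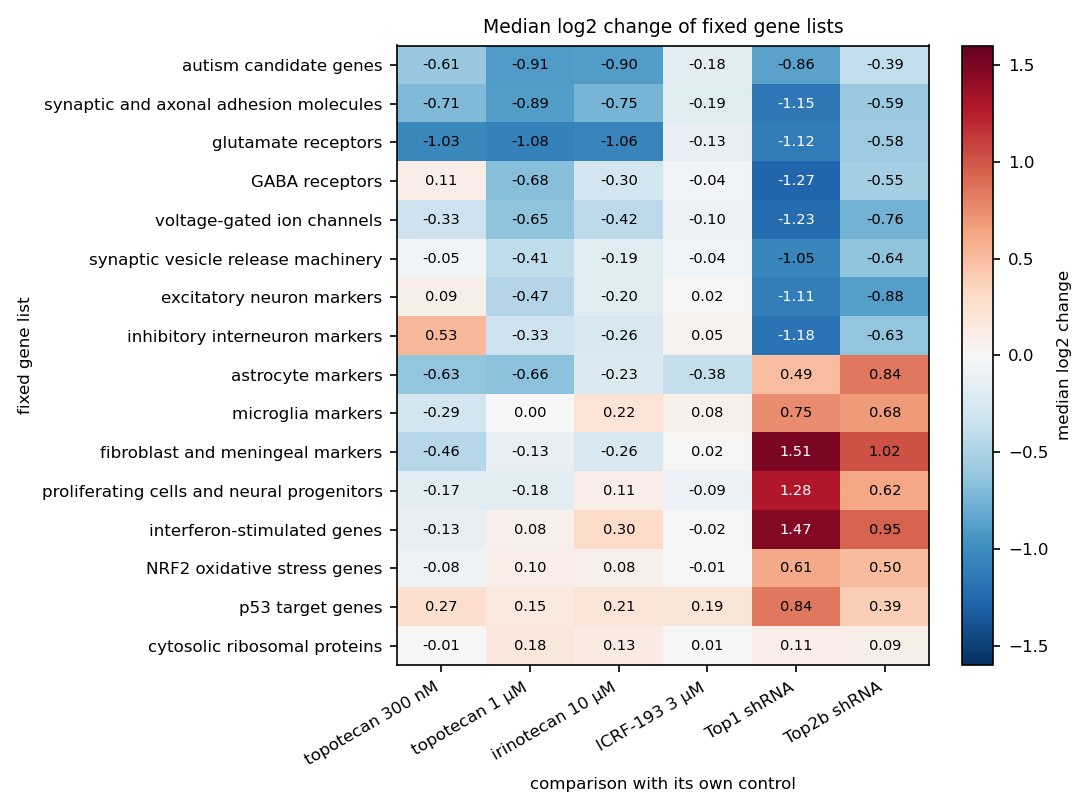
Median log2 change of fixed gene lists (vertical axis, colour and number) in the comparisons of groups (horizontal axis), each against its own control. Fibroblast markers had a median of 1.51 with Top1 shRNA and -0.13 with topotecan at 1 µM; with ICRF-193 the medians of NRF2 (-0.01) and interferon-stimulated genes (-0.02) turn to 0.01 and 0.02 after a new quantile normalization.

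Topotecan for 24 h, with and without washout, asked whether the changes reverse; each is 1 array against 2 vehicle arrays, and these and the other single arrays were not tested within their own experiments. At 24 h Erbb4 was 11-fold lower (-3.46), Nrg3 stood at -3.44, Ipw at -3.15 and Csmd1 at -3.09, and Txnip at 2.31. By a rule of a 2-fold difference 309 genes were lower, 258 of them over 100 kb, and 54 higher. The very long genes had a median of -1.78 and astrocyte markers of 0.07. After washout 0 of the 309 were still 2-fold lower, their median moved from -1.37 to -0.10, and 307 lay within 0.5 of vehicle. Of the 54 higher genes 51 lay within 0.5 after washout. The long-gene score differed from vehicle by -0.508 at 24 h and by -0.027 after washout. The median after washout was -0.16 for very long genes (random lists -0.06 to 0.02), -0.13 for adhesion molecules (-0.05 to 0.02) and -0.05 for genes over 200 kb (-0.02 to 0). Some lists not chosen for length lay as far out. Astrocyte markers stood at -0.18 (-0.07 to 0.05), against 0.07 at 24 h. Interneuron markers stood at -0.20, against -0.29 at 24 h, and activity-regulated genes at 0.25. Random lists give no spread between arrays, and arrays of 1 group have a pooled SD of 0.065 in the score. Whether a part of the drug's change remained cannot be told from 1 array. Ttr, a transport protein of the choroid plexus, stood at 1.82 after washout.

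DRB, an inhibitor of transcription elongation, hydrogen peroxide and paraquat, a redox cycling compound, were included beside the topoisomerase inhibitors. With DRB the median of all genes was -0.34 against its vehicle (-0.26 after a new quantile normalization), and changes are to be read relative to that. Immediate early genes stood far above it: Npas4 at 4.31 (19.8-fold), Fosb at 4.40 and Fos at 3.48, and the activity-regulated genes had a median of 2.08 where random lists gave -0.71 to -0.11. Egln3, an oxygen sensor, stood at -4.09 (17-fold lower), and the transporter gene Slco1c1 at -4.01, with a median of -1.56 for astrocyte markers. Genes over 100 kb had a median of -0.47 where random lists gave -0.42 to -0.35, and the long-gene score stood at -0.157 (-0.352 without the filter on dim genes, and -0.069 against genes matched on mean expression, where arrays of 1 group have a pooled SD of 0.065).

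With hydrogen peroxide the stress gene Chac1 stood at 3.90 and 3.32 against each vehicle array, and the amino acid transporter gene Slc7a3 at 3.81 and 2.49. The integrated stress list had medians of 0.71 and 1.05 and the proliferating cell list of -1.62 and -0.57, with Top2a at -3.03 and -1.45. With paraquat Chac1 stood at 3.62 and 3.03 and the integrated stress list at 0.24 and 0.49. The long-gene score differed by 0.098 and -0.082 with hydrogen peroxide and by 0.025 and -0.154 with paraquat, so its sign depends on the vehicle array. The vehicle arrays differed 2-fold for 2229 genes, with Slc17a7 at 5.1 and 9.74, Col1a1 at 9.87 and 7.87 and Gfap at 7.18 and 8.22, and the treated arrays are given against each of them for that reason.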

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

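The tests of explanations for the 3 patterns weighed first were all chosen only after the result was seen; the splits of the arrays were planned before.

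With topotecan at 1 µM 1281 of 1988 genes over 100 kb fell. A loss of neurons as the whole cause is argued against, since the neuronal genes over 100 kb changed by -0.98 relative to those up to 100 kb (95% bootstrap interval over genes, not arrays, -1.14 to -0.75). The 86 neuronal genes up to 100 kb had a median of -0.20, with 28 lower and 8 higher, so a part played by neuron loss is not excluded. A normalization that acts on a gene by its brightness alone is argued against, since the long-gene score differed by -0.489 (95% interval -0.521 to -0.457) against other genes matched on mean expression, where it was -0.499 against all; other steps of the authors' processing cannot be undone here. Of 100 splits of the 12 arrays only 1, the real one, called as many as 5207 genes (highest other 0). A chance division of these 12 arrays is thus argued against, though mixed splits hold drug arrays in both groups, which raises their spread. Nothing states that the replicates are separate cultures, so a chance difference between cultures is not excluded. Slower transcription through long genes could give this pattern, but that stays an untested hypothesis, as does a change in which neurons survive.

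With Top1 shRNA 12 of 19 fibroblast and meningeal markers rose, with a median of 1.51 and Ogn up 7.54-fold. The array set of replicate 1 as the whole cause is argued against, since the median within replicates 2 and 3 was 0.97 (95% bootstrap interval 0.84 to 1.63); this bound was restated after the value was seen. A lower share of neurons alone cannot be told apart from a change in other cells: the medians of 5 lists of other cell types with 67 genes spread from 0.49 to 1.51 (permutation p = 0.0431), and both the test and its stricter threshold of 0.01 were set after a first try. Of 10 splits of the arrays 1, the real one, called 1579 genes (highest other 0), and 10 splits are too few for a share under 0.05. Open are more fibroblasts, fewer neurons and a response to the knockdown or its delivery; the measured Top1 level within replicates 2 and 3 was 95.1 and 83.1% of control.

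With topotecan at 1 µM the Ube3a probe set used for the calls stood at 0.21 and the second, brighter in vehicle, at -4.73. A dim second probe set is argued against, since its lowest vehicle array lay at 9.49, which is 4.48 above the limit of 5.01 for dim genes. The second probe set moved in the same direction as the non-coding gene Ipw of the same imprinted region in 8 of 9 comparisons. A transcript that overlaps Ube3a on the other strand is a candidate explanation, but the place of the probes is not in the sources used here and comparisons share controls, so it cannot be told apart from a change within Ube3a. The rise of the probe set used for the calls rests on overlapping groups.

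In the 6 vehicle arrays of topotecan at 1 µM, vehicle 4 lay far from the others. Its long-gene score was 0.415 (others 0.476 to 0.498), and its mean log2 value was 8.393 for autism candidates (8.647 to 8.752), 8.101 for very long genes (8.396 to 8.479), 8.561 for adhesion molecules (8.917 to 9.002), 7.847 for glutamate receptors (8.216 to 8.347) and 8.719 for GABA receptors (9.136 to 9.278). It was 7.714 for ion channels (8.092 to 8.218), 8.507 for vesicle release (8.954 to 9.06), 7.43 for excitatory neuron markers (7.875 to 8.136) and, above the others, 8.399 for fibroblast markers (8.06 to 8.162). Vehicle 5 lay apart for activity-regulated genes at 7.478 (others 7.669 to 7.755). Among named genes 24 of 216 tests had an array apart, 14 of them from vehicle 4. Chance alone sets an array apart in about 1 in 20 groups, and here 11 of 52 tests of scores and lists did. Apart from the flag of vehicle 5 all of these came from vehicle 4, and the lists share genes. The tests are therefore not independent, and their share cannot be set against the rate by chance.

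The direct tests between treatments called genes with different effects. For topotecan at 1 µM and irinotecan these were 321. For topotecan at 300 nM and ICRF-193 they were 393, with a difference of the long-gene score of -0.478 (95% interval -0.743 to -0.213). Of 100 draws with labels permuted within each experiment 7 gave as many, so chance is not excluded, and the highest other draw called 1016, above the real count, which can point to a structure of the samples. A draw that exchanges drug and vehicle wholly in 1 experiment adds the effects of the treatments in place of taking their difference, and which draws gave many calls was not examined here or below. For topotecan at 1 µM and Top1 shRNA they were 2835, with a score difference of -0.279 (95% interval -0.412 to -0.145), and 4 of 100 draws gave as many (highest other 3232). That share is under the planned limit of 0.05 but close to it, and other draws exceeded the real count. Draws that keep or wholly exchange the labels of 1 experiment still carry its effect, so this test cannot decide whether chance is excluded. The score difference alone had a permutation p of 0.0624. Of 10 splits 1, the real one, gave the count for topotecan at 300 nM (480, highest other 0), for ICRF-193 (2031, highest other 0) and for Top2b shRNA (414, highest other 0), where 10 splits are too few for a share under 0.05. For the difference between Top1 and Top2b shRNA the real count was 0 by limma (806 genes at an unadjusted p under 0.05), with 17 as the highest other. Any split gives at least 0, so that all 10 of 10 splits did was fixed in advance and decides nothing. Among probe sets with no single gene symbol, which the comparisons do not use, 3056 of 17824 passed with topotecan at 1 µM, 2213 higher and 843 lower; no splits of the same sizes were run for these.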

How the results depend on the processing

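The array set block, shRNA replicates 2 and 3 alone and the 7 arrays of the larger dose set were chosen only after the values were seen. Of 353 values of main results under the alternatives, 257 kept their direction and side of the threshold (for counts, stayed within 1.5 times), 2 lost the call, 2 gained one, 86 moved and 6 turned sign. Of 7740 values of named genes 6502 stayed, 1201 lost the call, 33 gained one and 4 turned sign. Where not said otherwise the cause was not tested.

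Without the filter on dim genes the counts were 1286 for ICRF-193, 2226 for irinotecan, 614 for Top1 shRNA, 0 by limma for Top2b shRNA (2348 at an unadjusted p under 0.05 with the filter), 173 for topotecan against irinotecan and 244 for the dose trend. With 1 fit over all groups of a table they were 2657 for topotecan at 300 nM, 39 for ICRF-193, 1852 for topotecan at 1 µM, 452 for irinotecan, 4781 for Top1 shRNA, 2922 for Top2b shRNA and 331 for their difference. A minimum of 1.5-fold, which by its construction lowers counts, gave 144 for ICRF-193, 1378 for topotecan at 1 µM and 1117 for irinotecan. The replicate block gave 1 for topotecan at 300 nM, 4227 for topotecan at 1 µM, 2502 for irinotecan, 3124 for Top1 shRNA (1541 higher and 1583 lower) and 1352 for Top2b shRNA. Only for ICRF-193 did every number correlate more within itself than with other numbers and above 0.1. The array set block gave 3777 for Top1 shRNA, 1982 for Top2b shRNA and 2871 for the dose trend, where the sets were cut from the expression values themselves. Replicates 2 and 3 alone gave 5944, 3003 and, for the difference, 1888, and the 7 dose arrays gave 1127. The new quantile normalization gave 170 for topotecan against irinotecan, and log10 of the dose gave 217.

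With an estimated correlation the score difference lost camera's call for ICRF-193 (-0.086, unadjusted p = 0.239) and Top1 shRNA (-0.22, unadjusted p = 0.581), and of 80 calls of fixed lists 1 held. Genes over 200 kb gave Top2b shRNA a camera call (-0.198). The difference between topotecan at 1 µM and irinotecan in the score, 0.006, turned to -0.051 without the filter and -0.033 after quantile normalization, and to -0.001, 0, -0.003 and -0.006 without 1 array. The mean of a gene's probe sets turned Ube3a to -0.06 and Cntnap2 to -0.29 with ICRF-193, and Ube3a to -2.26 with topotecan at 1 µM and -2.48 with irinotecan. For single arrays the score moved, with DRB, to -0.352 without the filter and -0.069 against matched genes. At 24 h it moved to -0.405 without the filter, -0.498 with the mean of probe sets, -0.487 after quantile normalization, -0.847 for genes over 200 kb and -0.498 against matched genes; after washout it was -0.036 without the filter and -0.045 for genes over 200 kb. Of 420 list medians 10 turned sign after quantile normalization, the largest 0.09 in size.

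Leaving out 1 array gave 90 to 498 genes for topotecan at 300 nM, 885 to 2822 for ICRF-193, 4600 to 5893 for topotecan at 1 µM, 1780 to 3437 for irinotecan, 450 to 2486 for Top1 shRNA, 0 to 582 for Top2b shRNA and 0 for their difference. It gave 45 to 832 for topotecan against irinotecan, 136 to 1048 for topotecan against ICRF-193, 2314 to 4481 for topotecan against Top1 shRNA and 135 to 815 for the dose trend. The score difference ran from -0.627 to -0.487 for topotecan at 300 nM, -0.111 to -0.069 for ICRF-193, -0.511 to -0.489 for topotecan at 1 µM, -0.514 to -0.499 for irinotecan, -0.267 to -0.135 for Top1 shRNA and -0.136 to -0.055 for Top2b shRNA. It ran from -0.006 to 0.016 for topotecan against irinotecan, -0.082 to 0.098 for hydrogen peroxide, -0.154 to 0.025 for paraquat, -0.514 to -0.502 at 24 h and -0.033 to -0.021 after washout, and the correlation with dose from -0.93 to -0.9. A group left with 1 array is assumed to vary like the others. Genes whose mean over a whole table lay under the limits for dim genes (log2 of 7.04, 6.02 and 5.01) were left out. A called gene can still lie under the limit in 1 group, as Hapln1 with ICRF-193 at 5.26, and the background limits the size such a fall can reach.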

Other observations

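The 5 lists below were chosen only after the values were seen, and none of their 30 tests passed with an estimated correlation. With ICRF-193 genes of amino acid synthesis and tRNA charging fell: 21 of 26 fell and 0 rose, with a median of -0.22, including the folate enzyme Mthfd2 (-0.65), the transporter Slc7a3 (-0.57) and the serine enzyme Psph (-0.52); camera's adjusted p was 6.21e-13, and adjusted p = 0.155 with an estimated correlation. With topotecan at 300 nM the list had a median of -0.19 with 0 of 26 past the test over all genes (camera's adjusted p = 0.000443, and adjusted p = 0.589 with an estimated correlation). With hydrogen peroxide 19 of 25 of these genes were at least 2-fold higher, with medians of 1.34 and 1.31 against each vehicle array, and with paraquat 7 were, with medians of 0.87 and 0.74. Sterol synthesis genes fell in 9 of 19 cases with ICRF-193 (median -0.17) and in 6 of 18 with Top1 shRNA (median -0.77); camera's adjusted p was 2.35e-06 and 1.39e-06, and adjusted p = 0.253 and 0.38 with an estimated correlation. With Top2b shRNA 3 of 18 fell (median -0.89, camera's adjusted p = 6.7e-09), and adjusted p = 0.339 with an estimated correlation. With topotecan at 1 µM 9 of 18 fell and 1 rose (median -0.37, camera's adjusted p = 0.0019), and adjusted p = 0.589 with an estimated correlation. At 300 nM 0 of 19 passed, with a median of 0.20, and with irinotecan 1 of 18 fell, with a median of -0.06 (camera's adjusted p = 0.136). With paraquat 8 of 18 sterol synthesis genes were at least 2-fold higher, with medians of 1.30 and 0.63 against each vehicle array. With DRB 8 of 18 were at least 2-fold lower, with a median of -0.87 where that of all genes was -0.34, and at 24 h of topotecan the median was -0.52 with 0 at least 2-fold lower.

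Clustered protocadherins, adhesion genes that mark single neurons, fell in 10 of 21 cases with Top1 shRNA (median -1.19, camera's adjusted p = 6.7e-09, and adjusted p = 0.39 with an estimated correlation). Neuron markers lay as low there, with medians of -1.11 for excitatory neurons and -1.18 for inhibitory interneurons. With topotecan at 1 µM 8 of 21 fell and 0 rose (median -0.24, camera's adjusted p = 0.0197, and adjusted p = 0.617 with an estimated correlation), and with irinotecan 6 of 21 rose and 0 fell (median 0.18, camera's adjusted p = 0.0883), while the median was 0.02 at 24 h of topotecan; the drugs were not compared directly for this list. With DRB 17 of 21 were at least 2-fold lower, with a median of -1.37 where the median of all genes was -0.34. Collagen genes rose in 10 of 26 cases with Top1 shRNA (median 0.82) and in 6 of 26 with Top2b shRNA (median 0.46), beside the fibroblast markers given for these groups; camera's adjusted p was 4.55e-07 and 2.35e-06, and adjusted p = 0.1 for both with an estimated correlation. Collagen genes pointed down with topotecan at 300 nM, with 0 of 24 past the test over all genes (median -0.43, camera's adjusted p = 2.1e-05, and adjusted p = 0.351 with an estimated correlation), and with irinotecan 6 of 26 fell and 1 rose (camera's adjusted p = 0.00763, and adjusted p = 0.339 with an estimated correlation). With DRB 5 of 11 histone genes were at least 2-fold higher and 1, H2ac21, lower (-1.48), with a median of 0.81.

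The shRNA arrays of replicate 1 stood apart over probe sets without a gene symbol. Over 16010 of these the median correlation with the other 31 later gene-level arrays was 0.36, against at least 0.95 among the 3 arrays and at least 0.87 among the others. Over the 23521 probe sets with 1 symbol it was 0.95.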
